A study of Mus musculus with 73 samples.

How the data were processed

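The series holds 73 mouse samples. Per the labels, 47 are whole hippocampus, 19 are cortex (all cortical cells) and 7 are libraries of brain endothelial cells sorted from hippocampus. Groups were read from the sample titles, because the treatment field of all 31 samples of the LPS hippocampus table reads RP while the titles name 4 groups. Every one of the 73 samples was matched to a data column and used.

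Per the labels' protocols, hippocampal RNA was turned into cDNA with a SMART-seq v4 kit and cortical RNA with Smart-Seq2, both followed by Nextera XT libraries. The authors deposited raw counts per gene symbol for the bulk samples, without normalization. Per the submitters' processing notes, cortex reads were trimmed with Trim Galore 0.3.7 and aligned with STAR 2.5.3a to GRCm38, hippocampal reads were aligned with STAR 2.5.3a to mm10, and DESeq2 was used for both. The counting program and annotation are not stated in the sources used here. The endothelial libraries were deposited as UMI counts per gene and cell barcode, made with 10x Chromium v3 and, per the file headers, Cell Ranger 3.1.0, with Seurat 3.1 and mm10 in the processing notes. For sorting, cells were stained for CD31, CD45 and CD11b, dead cells were excluded, and the hippocampi of 4 to 5 mice per group were pooled. The deposited barcodes were already limited to 2327 to 5543 per library.

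The cortex table held 35486 genes and those of hippocampus 24411, in which 27 gene names had turned into dates in the spreadsheet; these held at most 0.32% of counts and were kept under neutral names. Depth per group (median, lowest and highest, in megacounts) was 23.3 (5.51 to 30.6) for SAL_SAL, 32.0 (16.9 to 50.9) for LPS_SAL, 19.5 (6.08 to 40.3) for LPS_CP, 20.0 (12.0 to 49.7) for LPS_RP, 17.9 (3.36 to 28.6) for CP, 20.5 (2.24 to 37.9) for RP, 5.74 (3.62 to 12.5) for cortex Sal, 4.34 (1.39 to 8.91) for cortex LPS and 5.20 (0.857 to 9.34) for cortex LPS+Clu. For 5 pairs of groups depth was tested and did not differ past the threshold (two-sided exact permutation p 0.108 or more); LPS_CP and LPS_RP were not tested against LPS_SAL. Sequencing reads without molecular identifiers are not independent molecules, so intervals cover counting error only. No pair of bulk samples within a group was a duplicate, pairs across groups and endothelial libraries were not checked, and the bulk samples had Xist at 1.54 CPM or less and Ddx3y at 43.25 CPM or more, as in males. The mitochondrial synthetase gene Lars2 took 6.49% to 10.8% of cortex counts and 0.119% to 0.332% of hippocampal counts.

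In the LPS hippocampus table the samples _1 and _2 of an L number were summed before testing, since the labels do not say whether they are separate animals. As deviations from group means, samples of an L number correlated at a mean of −0.08, against −0.15 between L numbers of a group. Of 30 samples 8 correlated best with their own L number, and the duplicate correlation was 0.167. Over all genes the samples thus shared little within an L number, and summing left fewer replicates. The genes raised by LPS were closer in some L numbers. In LPS_SAL their mean log2 CPM was 3.534 and 3.562 in L2 and 3.563 and 3.671 in L6. It was 3.297 and 3.234 in L10 and 3.266 and 3.362 in L14. Not every pair was close, with 3.215 and 2.855 in LPS_RP L12. For these genes, samples of an L number may therefore not be independent. Each bulk table was fitted with edgeR 4.0.16 in R 4.3.3: filterByExpr, TMM factors, robust quasi-likelihood fits over all groups of the table, and F tests of LPS_SAL minus SAL_SAL, LPS_CP minus LPS_SAL, LPS_RP minus LPS_SAL, LPS_RP minus LPS_CP, RP minus CP without LPS, cortex LPS minus Sal and cortex LPS+Clu minus LPS. Adjusted p-values are Benjamini-Hochberg over all genes tested, with a threshold of 0.05. Standard errors of log2 fold changes come from the F statistic. Group levels are mean CPM (counts per megacount of the library total) with SD. No batch, animal or pairing is given in the labels. Samples that share a number showed no clear shared deviation over all genes, so no main fit was paired.

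A total of 30 gene lists were fixed in advance: endothelial activation, cytokines, interferon response, MHC class I, complement, coagulation, reactive astrocytes, homeostatic and activated microglia, activity-dependent genes, neural progenitors, synapse, oligodendrocytes, glucocorticoid-responsive genes, blood-brain barrier, clusterin and lipoprotein receptors, arterial, capillary and venous endothelium, oxidative phosphorylation, heat shock and dissociation stress, and markers of choroid plexus, ependyma, pericytes, fibroblasts, red blood cells, leukocytes, astrocytes, thalamus and striatum, and dentate gyrus and CA fields. Some genes stand in several lists, for example Lcn2. Lists were tested with camera (limma 3.58.1; preset correlation 0.01, and an estimated correlation) and fry, adjusted over the lists of a comparison, and members were also adjusted over the list alone. The LPS-regulated sets are the genes called in the hippocampal LPS comparison. They were tested in RP minus CP, whose groups are outside that contrast, with camera and with a two-sided exact permutation of the mean log2 CPM per L number. For RP and CP plasma after LPS both contrasts came from the same fit, so the filter, TMM factors and dispersions were shared. In cortex the LPS samples were divided by the letters A and B in their names, and 20 simulations without a clusterin effect gave the value for shared libraries.

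The rule for named bulk genes was fixed in advance. It takes the 10 higher and 10 lower genes with the largest log2 fold change among those past the threshold with an average log2 CPM of 1 or more. It adds up to 4 members of each list with the smallest p past the threshold, and Clu, Lrp8, Lrp1 and Vldlr in any case; 1 further gene that the rule always takes is not reported here. In comparisons where no gene passed, the 5 genes with the smallest p in each direction stand in their place. Sex-linked, haemoglobin, ribosomal, mitochondrial and unnamed genes were tested but not ranked. Gene positions come from the RefSeq annotation of GRCm38.p6, in which 332 of 335 named symbols were found.

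Single-cell counts were handled in Python 3.11.15 with scanpy 1.11.5. Cells with at least 500 genes and at most 10% mitochondrial UMIs were kept. Scrublet's automatic threshold marked only 29 of 23320 cells, so the highest doublet scores up to a rate of 0.8% per 1000 cells were removed (22 to 235 per library), a choice made after seeing the scores. Cells of all libraries were clustered together (2000 variable genes, 30 components, 15 neighbours, Leiden resolution 0.8, no batch correction). Clusters were classed from marker lists and a class was named only where its markers led; 3 versions of the naming rule were tried after seeing the clusters, the last being used and the other two kept as alternatives. Clusters left unnamed held 1.00% of cells in Sal, 2.24% in LPS, 3.11% in LPS+Clu, 1.98% in WT, 0.492% in APP, 0.427% in APP+Sal and 0.645% in APP+Clu. Median UMIs per endothelial cell were 3536, 5315, 4784, 5934, 6301, 4266 and 3782 in the same order. UMIs of the class were summed per library, and log2 ratios of CPM plus a pseudocount of 10 were taken; a gene counted as different at an absolute log2 ratio of 1 or more and a mean of 20 CPM or more. List medians were set beside 10000 random lists matched in 20 bins of mean expression, whose 95% range is given. With 1 library per group no test between groups was made.

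The methods were tested on simulated data. Of genes changed 2-fold, 82% to 98% were recovered in the bulk comparisons, with 5 to 12 false calls beside 200 changed genes. Of genes changed 4-fold, 94% to 100% were recovered. Genes varied independently in the bulk simulations, so variation shared across genes is not covered and real recovery may be lower. Alternatives covered size factors, the low-count filter, DESeq2 1.42.0, fits of only the compared groups, each sample as a replicate, limma-voom with duplicateCorrelation, replicate blocks, omission of each replicate, set thresholds, cell filters, doublets, cluster naming, pseudocounts and thinning of cells to 2000 UMIs. After seeing the data, alternatives with a choroid plexus score, a Ttr minimum of 200 CPM, a minimum of 2000000 cortex counts and L numbers up to 8 as a factor were added. The human APP transgene cannot be read from counts on the mouse genome and was not analysed here.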

Results

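RNA was measured in 73 mouse brain samples. They were 47 bulk hippocampus samples, 19 bulk cortex samples and 7 single-cell libraries of sorted hippocampal endothelial cells. The series concerns plasma linked to exercise and the secreted protein clusterin, and how they alter brain inflammation after lipopolysaccharide (LPS, a bacterial outer-membrane component) or in mice that carry a mutant human amyloid precursor protein (APP). One hippocampal table held mice given saline only (SAL_SAL, 8 samples), LPS and saline (LPS_SAL, 8), LPS and the treatment labelled CP (LPS_CP, 7) and LPS and the treatment labelled RP (LPS_RP, 8). The labels do not spell out RP and CP, which are called RP and CP plasma here after the series title. The samples of that table carry L numbers, mostly with a pair of samples each, and the counts of an L number were summed, which left 4 L numbers per group. Another hippocampal table held RP and CP samples without LPS, 8 of each. The cortex table held Sal (4), LPS (8) and LPS with clusterin (LPS+Clu, 7). Depth was 5514214 to 50874577 counts per sample in the LPS hippocampus table, 2244822 to 37895128 in the RP and CP table and 856540 to 12515273 in cortex. Each endothelial library pooled 4 to 5 mice and stood alone in its group. After filtering, the endothelial class held 5096 cells in Sal, 3113 in LPS, 4388 in LPS+Clu, 3451 in WT, 2219 in APP, 1624 in APP+Sal and 2134 in APP+Clu. Comparisons, gene lists and the rule for naming genes were fixed before the data were examined. The labels do not say that samples come from separate animals, so p-values measure the spread between samples or L numbers, which may be technical.

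In hippocampus, LPS raised interferon, MHC class I, reactive astrocyte and endothelial activation genes and lowered homeostatic microglia and arterial genes. The question was what LPS alone does, as the background for both plasmas. With 4 L numbers per group, 1687 of 16180 genes passed at an adjusted p under 0.05, of which 1053 rose and 634 fell. Among genes with an average log2 CPM of 1 or more, the largest rises were those of Mmp3, a matrix metalloproteinase (log2 fold change 9.20 ± 1.37, SE), and Saa3, an acute-phase protein (8.07 ± 1.04). Il1rn, the antagonist of the interleukin-1 receptor (6.95 ± 1.32), the chemokine Ccl5 (6.31 ± 0.89), the nucleic acid sensor Zbp1 (5.37 ± 0.34), the chemokine Cxcl10 (5.35 ± 0.95) and the guanylate-binding protein Gbp2 (4.86 ± 0.39) also rose. Lcn2, an iron-carrier binding protein of acute inflammation, went from 15.06 ± 13.45 to 249.4 ± 98.73 CPM (counts per megacount of the library total, mean and SD; log2 fold change 4.08 ± 0.67, adjusted p 0.00142). The largest falls at the same level were those of Gpr34 (−2.44 ± 0.25), a microglial receptor, the fructose transporter Slc2a5 (−2.28 ± 0.30), the organic anion transporter Slco1a4 (−2.07 ± 0.20) and Tek (−1.96 ± 0.14), the receptor for angiopoietins. P2ry12, a receptor of resting microglia, went from 26.01 ± 2.782 to 6.82 ± 2.511 CPM (−1.93 ± 0.29). Abcb1a, the drug efflux pump of brain capillaries, went from 36.31 ± 2.317 to 10.83 ± 1.876 CPM (−1.75 ± 0.13). In the mouse genome build GRCm38.p6, Lcn2 lies on chromosome 2 from 32384637 to 32387739, P2ry12 on chromosome 3 from 59216271 to 59262985 and Abcb1a on chromosome 5 from 8567091 to 8748575.

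The interferon response moved as a block in hippocampus: all 30 measured members rose, both over all genes and adjusted over the list alone, with a median log2 fold change of 2.40 (camera, adjusted p = 0.00306 with an estimated correlation). Irf7, the master regulator of type I interferon genes, went from 2.141 ± 0.2609 to 41.12 ± 0.4029 CPM (adjusted p 6e-09), and Ifi44 (4.00 ± 0.27) and Oasl2 (2.90 ± 0.23) rose too. Irf7 lies on chromosome 7 from 141263183 to 141266499. All 13 genes of MHC class I antigen presentation rose (median 1.34; adjusted p = 0.0119 with an estimated correlation), among them their transactivator Nlrc5 (3.24 ± 0.26), the immunoproteasome subunit Psmb8 (2.23 ± 0.25) and B2m (0.77 ± 0.09), the light chain of class I molecules. All 25 reactive astrocyte genes rose (median 2.12; adjusted p = 0.00782 with an estimated correlation), including Aspg (3.11 ± 0.23), the oncostatin M receptor Osmr (3.15 ± 0.26) and Gfap, the astrocyte intermediate filament (492.9 ± 47.56 to 1389 ± 322.1 CPM). Of 24 complement and acute-phase genes 14 rose and 0 fell (16 and 1 adjusted over the list alone; median 1.23; adjusted p = 0.034 with an estimated correlation), among them C4b (1.19 ± 0.10), C5ar1 (2.16 ± 0.17) and complement factor Cfb (1.26 ± 0.17). Of 25 cytokine, chemokine and NF-kB feedback genes 16 rose (18 adjusted over the list alone; median 1.66), and camera's adjusted p of 9.16e-16 became an adjusted p = 0.11 with an estimated correlation. Of 15 glucocorticoid-responsive genes 10 rose and 0 fell (11 adjusted over the list alone; median 0.63; adjusted p = 0.00449 with an estimated correlation). They included Fkbp5, a co-chaperone of the glucocorticoid receptor (122.5 ± 8.055 to 230.7 ± 8.566 CPM), the cell cycle inhibitor Cdkn1a (1.95 ± 0.18) and the metallothionein Mt2 (1.94 ± 0.20). Of 20 coagulation and fibrinolysis genes 8 rose and 1 fell (9 and 2 adjusted over the list alone; median 0.22). Pros1, the cofactor protein S (1.15 ± 0.09), and the protease inhibitor A2m (3.40 ± 0.39) rose and von Willebrand factor, Vwf, fell (−1.38 ± 0.20); camera's adjusted p was 8.84e-05, and the adjusted p = 0.159 with an estimated correlation.

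Vessel genes moved in both directions. Of 24 genes of endothelial inflammatory activation 17 rose and 0 fell (20 and 0 adjusted over the list alone; median 1.54; adjusted p = 0.0195 with an estimated correlation), including Angpt2 (2.86 ± 0.20), which destabilises vessels, and the interleukin-4 receptor chain Il4ra (2.08 ± 0.16). Of 20 blood-brain barrier genes 7 fell and 3 rose (8 and 3 adjusted over the list alone; median −0.20). The falls included Slco1a4, Abcb1a and Itm2a (−1.46 ± 0.12), while the junctional cadherin Cdh5 rose (1.17 ± 0.09); camera's adjusted p was 0.000443, and the adjusted p = 0.074 with an estimated correlation. Of 14 arterial genes 7 fell and 0 rose (median −0.25; adjusted p = 0.0159 with an estimated correlation), among them Gkn3 (−3.32 ± 0.29) and Alpl (−0.79 ± 0.17). Of 10 capillary genes 2 rose and 1 fell (2 and 4 adjusted over the list alone; median −0.10; camera adjusted p 0.128, fry 0.0019), and of 10 venous genes 3 rose and 2 fell (median 0.04; adjusted p 0.787). Of 9 genes for clusterin and lipoprotein receptors 3 fell: the apolipoprotein E receptors Lrp8 (−0.17 ± 0.05, adjusted p 0.0207) and Vldlr (−0.24 ± 0.07, adjusted p 0.0399) and the microglial lipid sensor Trem2 (−0.80 ± 0.14). The list itself did not pass camera (adjusted p 0.0745) but passed fry, pointing down (adjusted p 0.00313). Clu, the gene for clusterin, was at 1198 ± 183 CPM against 1064 ± 82.04 (0.16 ± 0.08, adjusted p 0.269). Clu lies on chromosome 14 from 65968483 to 65981548 and Lrp8 on chromosome 4 from 107802200 to 107876840.

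Among cell type lists in hippocampus, 9 of 15 homeostatic microglia genes fell (11 fell and 1 rose adjusted over the list alone; median −0.50; adjusted p = 0.034 with an estimated correlation). Olfml3 (−0.96 ± 0.12) was among them. Of 20 activated microglia genes 6 rose (median 0.44), including Ms4a6d (3.82 ± 0.33) and the Fc receptor Fcgr1 (1.30 ± 0.14), with an adjusted p = 0.182 with an estimated correlation. Of 15 oligodendrocyte and myelin genes 4 fell and 1 rose (8 and 1 adjusted over the list alone; median −0.35; adjusted p = 0.268 with an estimated correlation); the myelin genes Mog (−0.56 ± 0.15) and Cnp (−0.38 ± 0.11) fell. Activity-dependent genes had 2 falls of 20, Nr4a3 (−0.44 ± 0.07) and the growth factor Bdnf (−0.35 ± 0.07), with a median of −0.20 and an adjusted p = 0.523 with an estimated correlation. Of 16 progenitor and immature neuron genes 2 fell (4 adjusted over the list alone; median −0.19; adjusted p = 0.14 with an estimated correlation), Ccnd2 and Sox2. Of 9 astrocyte genes 3 rose and 1 fell (3 and 3 adjusted over the list alone; median 0.05; camera adjusted p 0.0853, fry 0.00207). Of 11 pericyte and smooth muscle genes 3 fell (1 rose and 5 fell adjusted over the list alone; median −0.40; adjusted p = 0.268 with an estimated correlation), and of 16 heat shock genes 2 rose and 1 fell (4 and 1 adjusted over the list alone; median 0.13). Leukocyte genes had 1 rise and 2 falls of 13 (median 0.59), fibroblast genes 1 rise of 11 (median −0.28) and thalamus and striatum genes 1 rise of 12 (median −0.13). No member passed over all genes among 16 synapse genes (median −0.02), 20 oxidative phosphorylation genes (−0.03), 7 ependymal genes (−0.34), 10 dentate gyrus and CA genes (median −0.02, mean 0.01) and the 1 red blood cell gene measured (−0.98). All 12 choroid plexus genes lay below 0 (median −0.44; 0 passed; camera adjusted p 0.0559). Over all genes edgeR's count of 1687 went to 2760 with every sample as a replicate, and 17 of the 90 named genes, Lrp8 and Vldlr among them, lost their call when some L number was left out.

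In cortex, LPS raised interferon, endothelial activation, reactive astrocyte and glucocorticoid-responsive genes and lowered genes of resting microglia. With 8 LPS and 4 Sal samples, 506 of 15915 genes passed, of which 380 rose and 126 fell. Saa3 (7.57 ± 1.41), Lcn2 (0.8525 ± 0.8661 to 84.5 ± 24.77 CPM; 6.81 ± 0.48, adjusted p 1.48e-07), Zbp1 (5.28 ± 0.90), the metalloreductase Steap4 (4.64 ± 0.78) and Ch25h (3.99 ± 0.35), which makes an antiviral oxysterol, were among the largest rises, with Ccl5 (4.30 ± 1.03) and Scgb3a1 (4.03 ± 0.63). Itm2a (−1.74 ± 0.22), Edn3 (−1.64 ± 0.29), the flippase gene Atp10a (−1.59 ± 0.24), Abcb1a (−1.42 ± 0.19) and Tek (−1.42 ± 0.24) fell. P2ry12 fell from 35.45 ± 4.222 to 11.9 ± 1.275 CPM (−1.57 ± 0.11, adjusted p 1.49e-10).

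The interferon list rose in cortex with 20 of 28 members (28 adjusted over the list alone; median 1.40; adjusted p = 0.00142 with an estimated correlation), for example Irf7 (3.6 ± 0.28) and the antiviral membrane protein Ifitm3 (2.59 ± 0.23). Endothelial activation had 16 of 21 members up (20 adjusted over the list alone; median 1.5; adjusted p = 3.93e-05 with an estimated correlation), including Angpt2 (2.85 ± 0.31) and Lrg1 (2.24 ± 0.19). Glucocorticoid-responsive genes rose in 10 of 15 cases (13 adjusted over the list alone; median 0.66; adjusted p = 2.19e-05 with an estimated correlation), with Fkbp5 at 1.45 ± 0.10. Reactive astrocyte genes rose in 16 of 23 cases (19 adjusted over the list alone; median 1.57; adjusted p = 0.000417 with an estimated correlation) and MHC class I genes in 8 of 12 (10; median 0.72; adjusted p = 0.00389 with an estimated correlation). Complement genes rose in 10 of 21 cases (15 up and 1 down adjusted over the list alone; median 0.62; adjusted p = 6.46e-05 with an estimated correlation), for example C1qb (0.68 ± 0.08). Cytokine genes rose in 5 of 13 cases (9 up and 1 down adjusted over the list alone; median 0.84; adjusted p = 0.0156 with an estimated correlation) and coagulation genes in 4 of 15 (median 0.19; adjusted p = 0.0153 with an estimated correlation). Of 15 homeostatic microglia genes 4 fell and 2 rose (5 and 2 adjusted over the list alone; median −0.25; adjusted p = 0.0156 with an estimated correlation), Fcrls being among the rises (0.61 ± 0.10). Venous genes had 3 rises and 1 fall of 9 (median 0.03, mean 0.88, adjusted p = 0.00157 with an estimated correlation). Lcn2 (6.81), which stands in several lists, raises that mean, beside Il1r1 (1.01), Ctsc (0.93) and Car8 (−0.33). The list was not tested without Lcn2, so a venous shift beyond this gene is not shown.

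Other cortex lists passed camera only with its preset correlation. Blood-brain barrier genes had 7 falls and 2 rises of 20 (8 and 4 adjusted over the list alone; median −0.06; adjusted p = 0.102 with an estimated correlation), among them Bsg, the receptor basigin (−0.39 ± 0.06), and the lipid transporter Mfsd2a (0.55 ± 0.11). Activity-dependent genes had 5 falls of 20 (11 adjusted over the list alone; median −0.28; adjusted p = 0.0612 with an estimated correlation), including the transcription factor Egr2 (−1.06 ± 0.27) and Bdnf (−0.44 ± 0.12). Activated microglia genes had 3 rises of 12 (median 0.06; adjusted p = 0.102 with an estimated correlation), astrocyte genes 2 of 9 (median 0.04; adjusted p = 0.134 with an estimated correlation) and oligodendrocyte genes 1 fall of 15, Opalin (−0.98 ± 0.20; adjusted p = 0.508 with an estimated correlation). Lists that did not pass were arterial genes (1 fall of 10), capillary genes (1 rise and 1 fall of 10), heat shock genes (3 rises of 15; median −0.02, mean 0.13), leukocyte genes (1 rise of 4; median −0.19, mean 0.58) and fibroblast genes (1 fall of 11). The clusterin and lipoprotein receptor list had 0 changes of 8 over all genes, with Clu at 1149 ± 36.14 CPM against 1072 ± 37.3 (0.11 ± 0.04, adjusted p 0.258) and Lrp8 at −0.10 ± 0.07 (adjusted p 0.821). The test was edgeR's quasi-likelihood F test over all 19 cortex samples. Of the 66 named cortex genes 17 lost their call when some sample was left out, among them Ccl5, Egr2 and Bdnf, and 15 in another alternative, among them Ccl5, Egr2 and Opalin. Of 13017 genes tested in both tissues, 287 rose in both (792 in hippocampus, 357 in cortex; 21.7 would be shared if the calls were independent), 80 fell in both (535 and 121; 4.97) and 0 moved in opposite directions; whether the tissues differ in size of response was not tested.

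**Figure D1:**
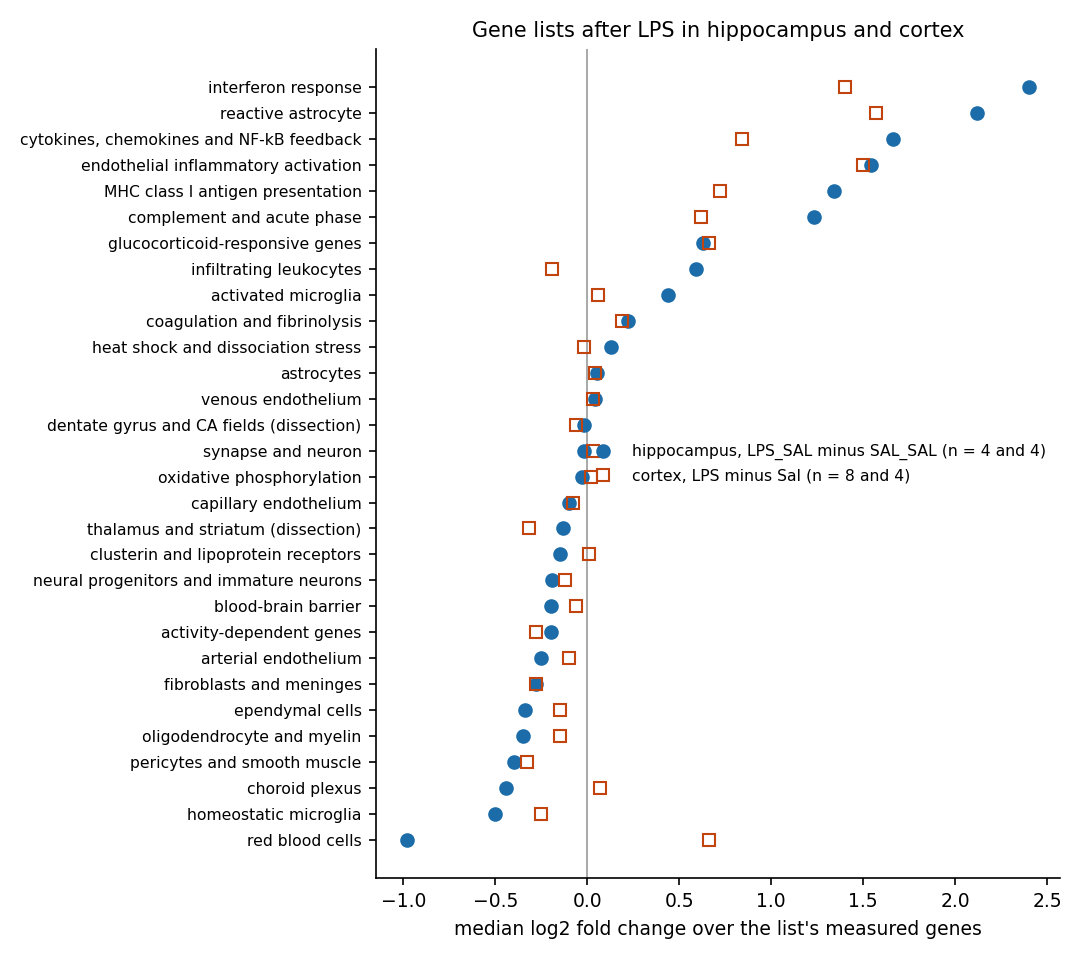
Median log2 fold change after LPS of the measured members of each gene list (horizontal axis), with 1 line per list; filled circles are hippocampus (LPS_SAL minus SAL_SAL, 4 L numbers each) and open squares cortex (LPS minus Sal, 8 and 4 samples). The interferon list lies at 2.40 in hippocampus and 1.40 in cortex, and the homeostatic microglia list at −0.50 and −0.25.

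CP plasma after LPS left the hippocampal transcriptome without a called gene. The question was whether CP plasma alters the state after LPS. In edgeR 0 genes passed for LPS_CP minus LPS_SAL, 294 of 16180 had an unadjusted p under 0.05, and DESeq2 and limma-voom also called 0. The smallest p-values, none of which passed (adjusted p 1), belonged to Aadat, an enzyme of kynurenine metabolism (0.414 ± 0.1509 against 0.1675 ± 0.03932 CPM), the cation channel gene Trpc6 (0.31 ± 0.09), Lss, a sterol synthesis enzyme (−0.21 ± 0.05), and the prostaglandin receptor gene Ptger3 (−0.80 ± 0.22). The interferon list had a median of −0.15 with 28 of 30 members below 0, and camera's adjusted p of 1.15e-08 went to an adjusted p = 0.981 with an estimated correlation. Reactive astrocyte genes (median −0.18), cytokine genes (−0.12), MHC class I genes (−0.16) and homeostatic microglia genes (0.10, 14 of 15 above 0) passed camera with its preset correlation and likewise had an adjusted p = 0.981 with an estimated correlation. Adjusted over the list alone, 0 members of any list passed. Clu stood at −0.03 ± 0.08. The heat shock list had a median of 0.01 and a mean of −0.04, and camera pointed up for complement (median −0.02) and down for leukocyte genes (median 0.10), none of them past the threshold. Tests on simulated data recovered 84% of genes changed 2-fold in this comparison, but there genes varied independently of one another. Variation that samples share across genes was left out, so the 84% may overstate the power here.

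RP plasma after LPS left no called gene against saline over all genes, and no list passed with an estimated correlation. In edgeR 0 genes passed for LPS_RP minus LPS_SAL (smallest adjusted p 0.242), while 1089 of 16180 had an unadjusted p under 0.05 and DESeq2 called 39, limma-voom 32, the fit with every sample as a replicate 46 and the fit of only these groups 9. The smallest p-values among lower genes belonged to the acute-phase genes Saa1 (0.8812 ± 0.252 against 2.874 ± 1.179 CPM; −1.65 ± 0.28) and Saa2 (−1.65 ± 0.33), the lipid enzyme gene Acat3 (−1.11 ± 0.21), the cationic amino acid transporter gene Slc7a2 (−0.49 ± 0.09) and the glycosyltransferase gene Ggta1 (−0.93 ± 0.18, adjusted p 0.254). Higher genes with the smallest p-values included Gfy (2.29 ± 0.48), Stoml3 (1.02 ± 0.22) and S100a5 (2.92 ± 0.66), which are known from olfactory neurons. The sample LPS_RP L8_2 stood apart with S100a5 at 4.31 CPM and Gfy at 2.859, against 1.159 and 1.078 or less in all other samples of the table. Clu stood at −0.15 ± 0.08 (adjusted p 0.87). Adjusted over the list alone, 21 of 30 interferon genes were lower (median −0.61, 0 above 0; 0 over all genes). The same count was 21 of 25 for reactive astrocyte genes (median −0.74), 16 of 25 for cytokine genes (−1.31), 12 of 13 for MHC class I genes (−0.65), 9 of 24 for endothelial activation (−0.50), 7 of 24 for complement (−0.41), 7 of 20 for activated microglia (−0.40) and 4 of 20 for coagulation (−0.28), with 0 over all genes in each. Homeostatic microglia genes were higher in 2 of 15 cases adjusted over the list alone (median 0.20). All of these lists passed camera with its preset correlation and none with an estimated one: the adjusted p = 0.0547 with an estimated correlation for interferon and for reactive astrocyte genes, 0.0652 for MHC class I, 0.072 for cytokines, 0.079 for homeostatic microglia and 0.0961 for endothelial activation. Leukocyte genes had the largest list median (−1.38, 3 of 13 above 0, camera adjusted p 0.0067) and an adjusted p = 0.316 with an estimated correlation. Fibroblast genes had 0 of 11 above 0 (median −0.17) and an adjusted p = 0.289 with an estimated correlation. Heat shock and dissociation stress genes had 0 of 16 above 0 (median −0.14), oxidative phosphorylation genes 20 of 20 (0.05), thalamus and striatum genes 10 of 12 (0.18) and dentate gyrus and CA genes 9 of 10 (0.09). These too passed camera, with adjusted p of 0.000247, 0.000466, 0.00453 and 0.00441, but had an adjusted p = 0.281, 0.289, 0.226 and 0.226 with an estimated correlation. The choroid plexus list had a median of −0.07, with camera pointing up. Because the LPS_SAL libraries also define the LPS effect, a sign opposite to that of LPS here is not independent of it.

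RP and CP plasma after LPS were also compared directly, in a contrast without LPS_SAL libraries, though the fit behind it held all groups of the table. In edgeR 0 of 16180 genes passed (smallest adjusted p 0.869), 867 had an unadjusted p under 0.05, and DESeq2 and limma-voom called 0. Saa1 (−1.41 ± 0.29), Saa2 (−1.56 ± 0.34), Acat3 (−0.99 ± 0.22) and the flavin monooxygenase gene Fmo1 (−0.61 ± 0.14) had the smallest p-values among lower genes, and the transcription factor gene Mlxipl (0.98 ± 0.24) and the clock output gene Dbp (0.38 ± 0.11) stood among the higher ones; none passed. Adjusted over the list alone, 10 of 13 MHC class I genes (median −0.49), 15 of 25 reactive astrocyte genes (−0.57), 9 of 24 complement genes (−0.38), 9 of 20 activated microglia genes (−0.48), 3 of 20 coagulation genes (−0.28), 3 of 11 fibroblast genes (−0.37), 1 of 10 venous genes (−0.35) and 1 of 9 astrocyte genes (−0.03) were lower with RP, against 0 in each over all genes. All 30 interferon genes lay below 0 (median −0.48), but 0 passed adjusted over the list alone. The adjusted p = 0.099 with an estimated correlation for MHC class I, reactive astrocyte, complement, coagulation and activated microglia genes, 0.174 for fibroblast genes, 0.141 for interferon, 0.143 for cytokines (median −1.28) and 0.0538 for venous genes. Leukocyte genes again had the largest list median (−1.48, 5 of 13 above 0, camera adjusted p 0.0111) and an adjusted p = 0.361 with an estimated correlation. Heat shock and dissociation stress genes had 0 of 16 above 0 (median −0.13, camera adjusted p 4.55e-05) and thalamus and striatum genes 10 of 12 (0.12, camera adjusted p 0.00452), with an adjusted p = 0.213 and 0.207 with an estimated correlation. Clu stood at −0.12 ± 0.08 and Lrp8 at −0.03 ± 0.05.

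The genes that LPS had raised in hippocampus were lower with RP than with CP plasma as a set. Of the 1053 genes, 853 had a negative RP minus CP log2 fold change, with a median of −0.186 (−0.248 to −0.092 with 1 L number left out, the latter without LPS_CP L15; camera p 6.8e-30 with the preset correlation; p = 0.0317 with an estimated correlation, fry p 0.0514). Per L number, the mean log2 CPM of these genes was 3.04 ± 0.07 (SD, n = 4) with RP and 3.30 ± 0.24 (n = 4) with CP, and the two-sided exact permutation p was 0.0857, where the smallest that 4 against 4 allows is 0.0286. Over single samples the means were 3.05 ± 0.13 (n = 8) and 3.28 ± 0.27 (n = 7), with an exact permutation p of 0.0471 that treats the samples of an L number as separate. Within L numbers up to 8 the difference was −0.17 and within those over 8 it was −0.34, and the exact permutation p within these strata was 0.111. For the 634 genes lowered by LPS the median was 0.041, with 414 above 0 (p = 0.254 with an estimated correlation), and it was −0.007 without LPS_CP L15. The choroid plexus score, the mean log2 CPM of that list, was 5.38 ± 0.39 with RP and 4.97 ± 1.20 with CP (exact permutation p 0.514, n = 4 each).

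**Figure D2:**
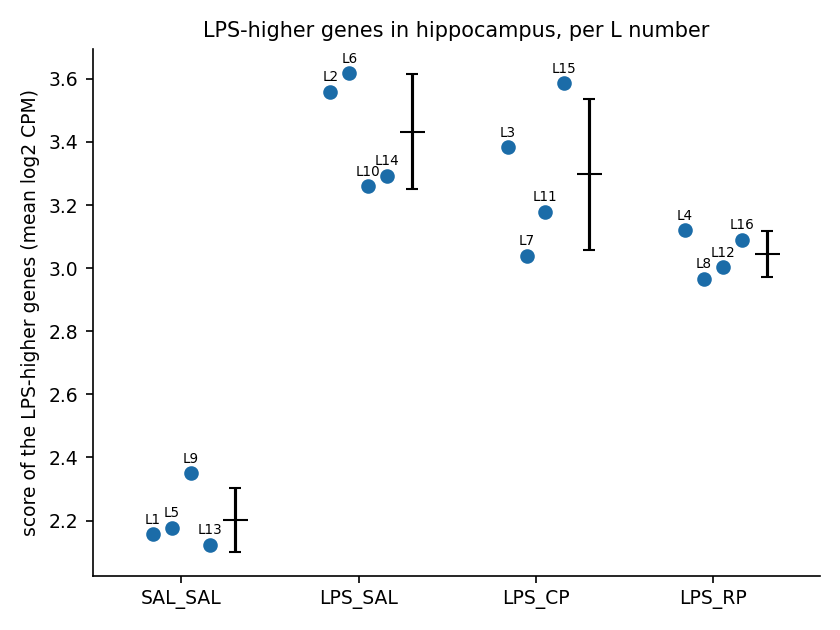
Mean log2 CPM of the genes raised by LPS (vertical axis) for each L number, labelled, in the 4 hippocampal groups, with the group mean and SD as bars; the genes were chosen on LPS_SAL against SAL_SAL, so those groups are not independent of the set. The LPS_RP points average 3.04 and the LPS_CP points 3.30.

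Without LPS, nearly all called genes were lower with RP than with CP plasma. The question was what RP plasma changes in unchallenged hippocampus. With 8 samples per group, 140 of 14647 genes passed in edgeR, of which 136 were lower and 4 higher with RP. The largest falls included those of the kinase gene Nek5 (−1.64 ± 0.32, adjusted p 0.0268), Pifo (−1.59 ± 0.29, adjusted p 0.0208), the dynein-associated Wdr63 (−1.58 ± 0.35), Mlf1 (−1.20 ± 0.24), Mycbpap (−1.11 ± 0.22) and the ciliary filament gene Tekt1 (−0.94 ± 0.20). The myosin gene Myo5c (−1.59 ± 0.29), the sugar phosphate transporter gene Slc37a2 (−1.37 ± 0.30), the polarity gene Llgl2 (−1.09 ± 0.22), the complement protease gene C1s1 (−1.18 ± 0.23), A2m (−0.98 ± 0.21) and the phosphatase gene Alpl (−0.54 ± 0.12) fell too. The 4 rises were Foxo6, a forkhead factor of hippocampal neurons (0.27 ± 0.05), Fam19a2 (0.25 ± 0.06), the neuropeptide gene Cck (154.5 ± 10.21 against 138.1 ± 5.762 CPM; 0.18 ± 0.04, adjusted p 0.0401) and the growth cone gene Basp1 (0.17 ± 0.04). Clu (−0.13 ± 0.05, adjusted p 0.195) and Lrp8 (−0.11 ± 0.04, adjusted p 0.164) did not pass. Nek5 lies on chromosome 8 from 22073615 to 22125418.

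Choroid plexus markers moved with the same groups. Ttr, the thyroid hormone carrier made by choroid plexus, was under 200 CPM in 5 of 8 RP samples and 0 of 8 CP samples. In the other hippocampal table Ttr was under 200 CPM in 1 of 8 SAL_SAL and 2 of 8 LPS_SAL samples. The same held there for 2 of 7 LPS_CP and 2 of 8 LPS_RP samples. Without LPS the choroid plexus score was 3.79 ± 2.31 with RP and 6.64 ± 0.50 with CP (two-sided exact permutation p 0.0103, n = 8 each). Of 12 choroid plexus genes 0 passed over all genes and 10 were lower adjusted over the list alone (median −2; adjusted p = 0.358 with an estimated correlation), and of 7 ependymal genes 1 fell (2 adjusted over the list alone; median −0.51; adjusted p = 0.358 with an estimated correlation). Complement genes had 1 fall of 23 (3 adjusted over the list alone), coagulation genes 1 of 19, arterial genes 1 of 14 and activated microglia genes 0 of 14 (4 adjusted over the list alone). Activity-dependent genes had 19 of 20 members above 0 (median 0.16) and synapse genes 14 of 16 (median 0.06); both passed camera, with an adjusted p of 0.000112 and 0.00224, and had an adjusted p = 0.358 with an estimated correlation, with 0 members called. With the choroid plexus score as a covariate the count of 140 went to 0, and with only the samples at 200 CPM of Ttr or more it went to 0, both chosen after seeing the data. The Ttr minimum left 3 RP samples, so its count of 0 cannot tell a lost difference from lost power. There the 136 lower genes had a median log2 fold change of −0.24 (quartiles −0.40 to −0.16), against −0.65 in all samples. Leaving out 1 sample gave 43 called genes without CP1, 48 without CP2, 89 without CP4, 31 without CP6, 3 without CP7, 20 without CP8, 24 without RP1, 10 without RP2, 619 without RP3, 410 without RP4, 7 without RP5, 6 without RP6 and 3 without RP7. Each of the 18 genes that the naming rule picked here lost its call when some sample was left out. The genes raised by LPS in the other hippocampal table had a median of −0.027 here (853 genes, 503 below 0; p = 0.222 with an estimated correlation), and those lowered a median of −0.006 (619 genes; camera p 0.491). Ttr lies on chromosome 18 from 20664209 to 20674326.

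**Figure D3:**
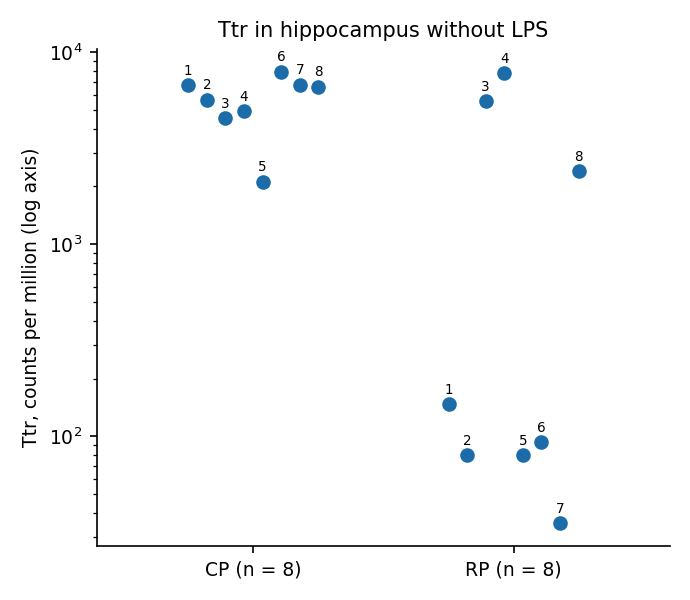
Ttr in CPM on a log axis for each of the 8 CP and 8 RP hippocampal samples without LPS. The CP points lie between 2114 and 7892 CPM, and 5 RP points lie between 35.4 and 147 CPM.

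Clusterin after LPS left no called gene in cortex. With 7 LPS+Clu and 8 LPS samples, edgeR and DESeq2 both called 0 of 15915 genes, and 705 had an unadjusted p under 0.05. The smallest p-values, all with an adjusted p of 1, belonged to Mxd4, a MYC antagonist (0.19 ± 0.05), the collagen gene Col6a1 (0.36 ± 0.09), Efr3a, a membrane anchor of a lipid kinase (−0.26 ± 0.06), and the prohormone convertase gene Pcsk1 (−0.33 ± 0.09). Clu itself stood at 1110 ± 60.95 CPM against 1149 ± 36.14 (−0.04 ± 0.04). Reactive astrocyte genes had a median of −0.24, with 3 of 23 above 0, and thalamus and striatum genes a median of 0.35, with 11 of 11 above 0; camera's adjusted p was 0.000109 and 0.000183, and each had an adjusted p = 0.839 with an estimated correlation. Cytokine (−0.15), interferon (−0.09), MHC class I (−0.12), oligodendrocyte (0.13) and dentate gyrus and CA genes (0.09) also passed camera with the preset correlation and had an adjusted p = 0.839 with an estimated correlation. Adjusted over the list alone, 0 members of any list passed. For the LPS-regulated genes, the LPS samples were divided by their letter, so that no library served both to choose and to test them. The 284 genes raised in LPS samples A had a median of 0.003 in LPS+Clu minus LPS samples B (camera p 0.982). The 222 raised in samples B had a median of −0.063 against samples A (p = 0.44 with an estimated correlation). With the same LPS libraries on both sides the median was −0.049, and 20 simulations with no clusterin effect gave −0.039 (range −0.05 to −0.028). For lowered genes the medians were −0.042 (68 genes) and 0.036 (34 genes), neither past the threshold; with the same libraries on both sides the median was 0.034, below the simulated mean of 0.055 and outside its range of 0.042 to 0.073.

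The 7 endothelial libraries carry no replicates, so no test between groups was possible, and each ratio may hold differences between pools. Intervals are 95% exact Poisson intervals and cover counting error only. Molecules (UMIs) of the endothelial class were summed per library, and log2 ratios were taken of CPM plus 10. In Sal the class lay mostly in clusters 0 (48.9%) and 2 (28.5%), in LPS in clusters 14 (35.8%), 15 (34.6%) and 11 (18.4%), and in LPS+Clu in clusters 14 (58.4%) and 15 (31%). In WT and APP cluster 3 held 65.9% and 59.5% and cluster 5 held 20.5% and 26.9%, and in APP+Sal and APP+Clu cluster 4 held 42.7% and 36.7% and cluster 2 held 19.4% and 23.4%. Of 6251 genes at a mean of 20 CPM or more, 637 differed 2-fold or more between LPS and Sal, 320 higher and 317 lower with LPS. Lcn2 was at 78.24 CPM in Sal (interval 74.26 to 82.38) and 9558 in LPS (9512 to 9604), a log2 ratio of 6.76. The chemokine Cxcl10 was at 1.404 CPM (0.9171 to 2.057) and 360.4 (351.5 to 369.5; 5.02), the apolipoprotein Apod at 137.9 and 4196 (4.83), Angpt2 at 11.34 and 397.8 (4.26) and the chemokine receptor Ackr1, a venule marker, at 7.884 and 314.5 (4.18). Bsg was at 13060 CPM in Sal (13010 to 13110) and 1044 in LPS (1029 to 1060; −3.63), Itm2a at 2887 and 470.7 (−2.59), and Lrp8 at 197.8 (191.5 to 204.4) and 31.75 (29.15 to 34.52; −2.32). The organic anion transporter Slc22a8 (−2.66), the capillary gene Spock2 (−2.64) and the chemokine Cxcl12 (−2.50) were lower too. Clu was at 52.81 CPM in Sal (49.55 to 56.23) and 93.86 in LPS (89.34 to 98.54; 0.73). Bsg lies on chromosome 10 from 79704358 to 79711979 and Cxcl10 on chromosome 5 from 92346638 to 92348889.

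Of 20 endothelial activation genes 18 were at least 2-fold higher in LPS and 0 lower (median 2.59, against −0.31 to 0.17 for random lists of like expression). The same held for 22 of 28 interferon genes (median 1.49; Irf7 94.17 to 1033 CPM), 10 of 12 MHC class I genes (1.42), 11 of 15 reactive astrocyte genes (1.53), 6 of 10 cytokine genes (1.13), 3 of 6 complement genes, 4 of 13 glucocorticoid-responsive genes (0.56), 1 of 8 coagulation genes (0.54) and 7 of 16 heat shock genes, of which 1 more was lower (0.98). Blood-brain barrier genes were lower in 10 of 19 cases and higher in 0 (median −1.28), capillary genes lower in 7 of 10 (−1.5), arterial genes lower in 5 of 10 and higher in 1 (−1.01), and venous genes higher in 1 and lower in 1 of 9 (0.32). Oxidative phosphorylation had 0 of 20 genes past 2-fold (−0.36), and 2 of 5 clusterin and lipoprotein receptor genes were lower (−0.40).

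Between LPS+Clu and LPS, 13 of 5861 genes differed 2-fold or more, 3 higher and 10 lower with clusterin. The higher genes were the phosphatase Dusp2 (30.19 CPM, interval 27.65 to 32.89, in LPS and 84.58, 80.79 to 88.5, in LPS+Clu; 1.23), the transcription factor Cebpb (1.09) and the chemokine Cxcl2 (1.02). Among the lower genes were the transferrin receptor Tfrc (134.6 CPM, 129.2 to 140.2, and 42.25, 39.58 to 45.04; −1.47), the heat shock gene Hsph1 (−1.28), Hmcn1 (−1.26), Ndnf (−1.12) and Atp10a (−1.05). Members of the activation list did not all move one way: Lcn2 went from 9558 to 14130 CPM (0.56), Ch25h by 0.73 and Socs3, a brake on cytokine signalling, by 0.82, while the adhesion genes Vcam1 (369.8 to 233.5 CPM) and Selp (34.82 to 15.62 CPM; −0.81) were lower. The activation list had a median of 0.25 (random lists −0.12 to 0.05), with 1 of 22 past 2-fold, blood-brain barrier genes a median of −0.34 (1 of 19 lower), capillary genes −0.43 (1 of 10 lower) and interferon genes −0.07. Heat shock and dissociation stress genes had a median of −0.12 (random lists −0.12 to 0.08; 1 of 16 lower), with Hsph1 at −1.28, Hspa1b at −0.96, Hspa1a at −0.94 and Hsp90aa1 at −0.71. Lrp8 went from 31.75 to 14.22 CPM (−0.79) and Clu by −0.46. Haemoglobin genes made up 3 of the 10 (Hbb-bs 171 to 0.5416 CPM), and their sign turned when doublets were kept (0.51 for Hbb-bs). The count of 13 went to 47 when clusters led by a marker of another class were left out, which was chosen after seeing the data, to 25 with a pseudocount of 1 and to 6 at a mean of 50 CPM. When the genes 2-fold higher in LPS were chosen with one part of the LPS cells and tested against the rest, their median was 0.166 (318 genes, 72 below 0; random lists −0.05 to 0.00), and the 223 genes lower in LPS had a median of −0.344 (10 above 0; random lists −0.10 to −0.05). With cluster 11, which held 572 LPS cells, left out and the sets chosen anew, the medians were 0.069 (359 genes) and −0.137 (276 genes). Dusp2 lies on chromosome 2 from 127336159 to 127338377 and Tfrc on chromosome 16 from 32608896 to 32632794.

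**Figure D4:**
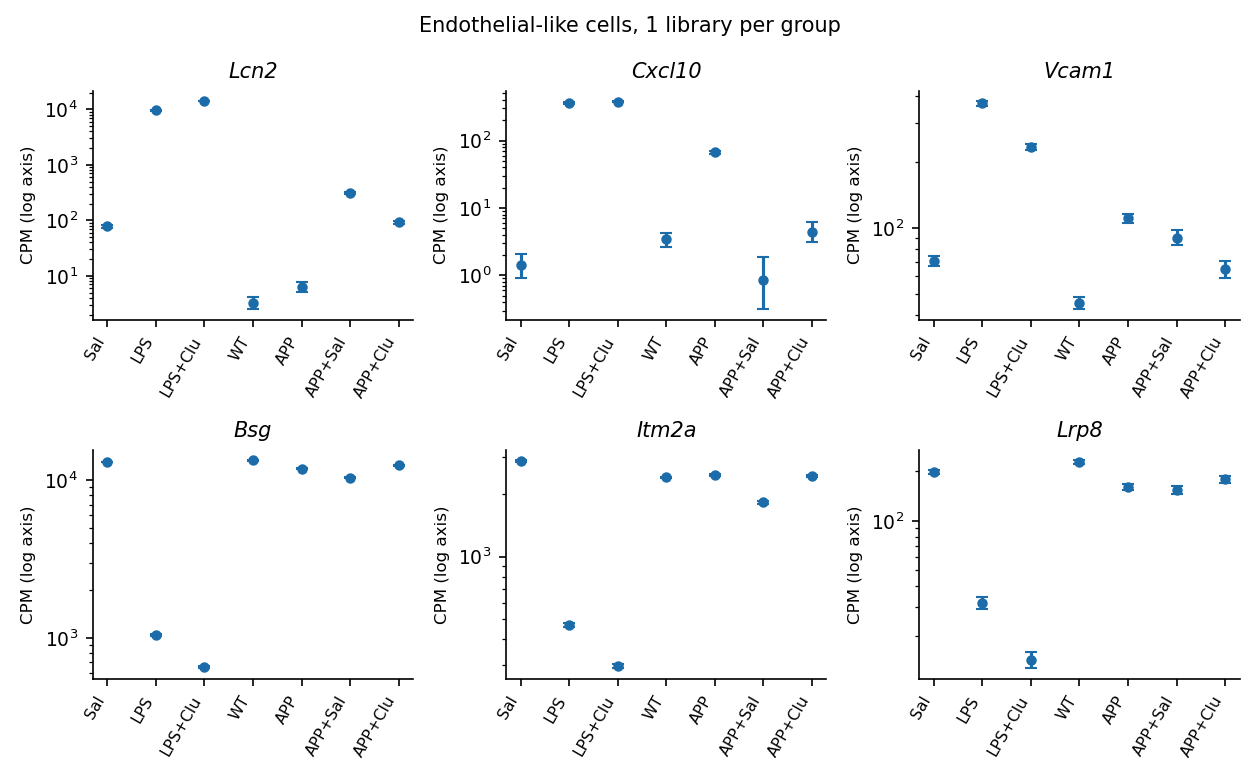
CPM on a log axis of Lcn2, Cxcl10, Vcam1, Bsg, Itm2a and Lrp8 in the endothelial class of the 7 libraries, 1 library per group, with 95% exact Poisson intervals for counting error as bars. Lcn2 is at 9558 CPM in LPS, 14130 in LPS+Clu and 78.24 in Sal, and Bsg at 1044 CPM in LPS and 13060 in Sal.

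All measured interferon and MHC class I genes were higher in APP than in WT endothelium. Of 6635 genes 15 differed 2-fold or more, 9 higher and 6 lower, and 24 did with a pseudocount of 1. Cxcl10 was at 3.422 CPM in WT (interval 2.672 to 4.316) and 66.56 in APP (62.37 to 70.96; 2.51) and Vcam1 at 45.35 (42.5 to 48.34) and 110.4 (105 to 116; 1.12). The class I genes H2-Q7 (1.45) and H2-Q6 (1.34), which are paralogs and may share reads, Ifi27l2a (1.33), the matrix protein gene Mgp (1.27), Ifit2 (1.21) and Ifit3 (1.05) were higher. Plvap, a component of fenestrated vessels, was at 38.99 CPM in WT and 2.481 in APP (−1.97), and Plpp3 at −1.06. Cluster 7, led by Plvap, held 50 WT cells and 1 APP cell, and cluster 1, with Vcam1, Icam1 and H2-Q7 among its top genes, held 1.6% of the class in WT and 2.9% in APP. All 27 interferon genes (median 0.44) and all 12 MHC class I genes (0.57) were higher, 3 of the former past 2-fold. Endothelial activation had a median of 0.41, arterial genes 0.37, venous genes 0.38, oxidative phosphorylation genes 0.17 with 20 of 20 above 0, and blood-brain barrier genes −0.07. Clu was at 109.6 CPM in WT (105.1 to 114.2) and 173.6 in APP (166.8 to 180.6; 0.62) and Lrp8 at 227.4 and 161.3 (−0.47). Red blood cell genes had a median of −5.08 (Hbb-bs 1745 to 17.3 CPM).

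In APP mice, endothelium of the clusterin library had less of several acute inflammatory transcripts than that of the saline library. Of 6305 genes 14 differed 2-fold or more, 5 higher and 9 lower with clusterin. Apod was at 460.2 CPM in APP+Sal and 125.7 in APP+Clu (−1.79), Ch25h at 132.1 (interval 123.7 to 140.9) and 34.29 (30.41 to 38.51; −1.68) and Lcn2 at 310.1 (297.2 to 323.4) and 91.39 (84.99 to 98.14; −1.66). The protease gene Adamts9 (−1.77), Scgb3a1 (−1.35), Lrg1 (−1.15) and the urokinase receptor gene Plaur (−1.01) were lower too. In the untreated APP library Lcn2 was at 6.379 CPM, Ch25h at 9.357 and Apod at 130.6. With clusterin Lcn2 and Ch25h thus stayed above untreated APP, while Apod lay near it. The lower levels are relative to the saline library and do not show a fall below untreated APP. Higher genes were Ttr (30.02 to 114.6 CPM; 1.64), the pericyte gene Rgs5 (32.17 to 93.68; 1.30) and 3 haemoglobin genes; the sign of Ttr turned under several alternatives, for example −1.61 with stricter cell filters. The activation list had a median of −0.60, with 4 of 18 past 2-fold lower (random lists −0.05 to 0.09), interferon genes −0.15 with 1 of 27 above 0, glucocorticoid-responsive genes −0.24 and heat shock genes −0.26. Capillary genes had a median of 0.36 with 9 of 10 above 0 and blood-brain barrier genes 0.16 with 16 of 19 above 0. Lrp8 stood at 0.20 and Clu at −0.29. Of the 9 genes higher in APP than WT, 7 passed the expression filter here and all 7 were lower with clusterin (median −0.424; random lists −0.10 to 0.14). Cxcl10, which had the largest ratio of APP to WT, was under that filter and went the other way, at 0.8578 CPM in APP+Sal (0.3148 to 1.867) and 4.467 in APP+Clu (3.145 to 6.157). Dbp, also under it, was at 5.289 and 6.036 CPM. The 5 genes lower in APP, mostly haemoglobin, had a median of 2.199, which ran from 0.711 to 2.615 under 5 alternatives and had too few genes under 4. The haemoglobin ratios turned with doublets kept (−1.14 for Hbb-bs). Ch25h lies on chromosome 19 from 34473783 to 34475148 and Apod on chromosome 16 from 31296192 to 31314808.

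The saline-treated APP library stood apart from the untreated APP library, and so did the clusterin-treated one. The pools also differed in sex: Xist, made from the inactive X chromosome of females, was at 279.1 CPM in APP and 0 in APP+Sal, and Ddx3y, on the Y chromosome, at 62.66 and 95.5. The ratios below therefore cannot be assigned to saline alone. Of 6497 genes 116 differed 2-fold or more, 59 higher and 57 lower in APP+Sal. By the same measure APP+Clu differed from APP in 102 genes, APP from Sal in 99 and WT from Sal in 69. A difference of this size is therefore not particular to the saline library. Lcn2 was at 6.379 CPM in APP (interval 5.13 to 7.841) and 310.1 in APP+Sal (297.2 to 323.4; 4.29), and Scgb3a1 (3.90), Ch25h (2.88), Cebpd (2.61) and the glucocorticoid-induced genes Zbtb16 (2.16) and Sult1a1 (2.10) were higher. Cxcl10 was at 66.56 and 0.8578 CPM (−2.82), and the clock genes Dbp (−2.44), Nr1d1 (−1.91) and Nr1d2 (−1.84) and the stress factor gene Atf3 (−2.06) were lower. Endothelial activation genes were higher in 8 of 18 cases (median 0.76), glucocorticoid-responsive genes in 3 of 10 (0.68), and interferon genes were lower in 2 of 27 (−0.55). MHC class I genes had a median of −0.46, activity-dependent genes −0.52 with 3 of 10 lower, arterial genes −0.47 and heat shock genes −0.32. In APP+Sal 606 cells were removed for mitochondrial reads and in APP+Clu 367, against 21 to 103 elsewhere.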

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

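Among the tests below, the choroid plexus covariates, the exact permutation over L numbers and the thinning of UMIs were chosen only after the result they test was seen; the regroupings of samples, the depth covariate, the correlation in the other hippocampal table and the omission of a cluster were chosen before.

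A gap test was run 72 times, on several quantities in each bulk group of 4 to 8 samples. In 7 of the tests a sample was set apart from its group, where chance does so in about 1 in 20. The tests share samples and are not independent of one another. Gfap in SAL_SAL L1_2 was at 599.8 CPM, with the other samples of the group at 428.5 to 500.7. Lcn2 was at 26.07 CPM in CP1 (others 0.559 to 7.801), at 19.45 in RP1 (others 0.1173 to 2.582), at 117.6 in cortex LPS+Clu A3 (others 51.97 to 80.08) and at 2.143 in cortex Sal B2 (others 0.3154 to 0.5517). The score of the LPS-raised genes was 2.419 in SAL_SAL L9_2 (others 2.069 to 2.233), and the choroid plexus score was 5.515 in CP5 (others 6.442 to 7.043).

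The first pattern is the 136 genes lower with RP than with CP plasma without LPS. Regrouping the 16 samples gave as many calls in 1 of 100 splits, the real one with 140 calls, and the highest other split had 58, so a random grouping is an unlikely source. With the choroid plexus score as a covariate 0 of them stayed called and their median log2 fold change went from −0.65 to −0.17, while with sequencing depth as a covariate 136 stayed called at −0.63. In the LPS table, whose samples played no part in choosing the genes, their median correlation with the choroid plexus score was 0.74, against −0.02 for all genes. These values go with unequal amounts of choroid plexus in the dissected pieces. Low Ttr also arose without plasma: in SAL_SAL it was 69.57 CPM in L1_1 and 5893 in L1_2. In LPS_SAL it was 30.75 CPM in L10_2 and 3759 in L10_1. Nor was Ttr low in every RP sample, with 3 of 8 over 1000 CPM. That argues against RP plasma as the only source of low Ttr. An effect of RP plasma on choroid plexus in addition cannot be told apart here.

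The second pattern is the lower level of LPS-raised genes with RP than with CP plasma after LPS. The choroid plexus covariate left the median at −0.20, from −0.186, so unequal choroid plexus may be set aside for this set. The exact permutation p over L numbers was 0.0857, so differences in LPS response between L numbers by chance could account for it. Between consecutive L numbers, a pairing the labels do not give, RP lay below CP each time. RP and CP scores were 3.12 and 3.384 (L4, L3), 2.967 and 3.039 (L8, L7), 3.003 and 3.179 (L12, L11) and 3.09 and 3.587 (L16, L15). The score was not tested with this pairing. A biological effect of RP plasma remains possible, and 4 L numbers per group cannot decide between the alternatives.

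The third pattern is that genes changed by LPS in endothelial cells lay further from Sal in the LPS+Clu library than in the LPS library. Without cluster 11, which was almost confined to the LPS library, the median of the LPS-higher genes was 0.069 in a set chosen anew (359 genes), against 0.166 in the set with all clusters (318 genes), and still above the random range of −0.04 to 0.00, so the cluster may not account for all of it. With all cells thinned to the same number of UMIs the median was 0.181. Library sums were scaled to CPM with or without thinning, so thinning mainly changes how much deep cells weigh. That weight is not a likely source. Other differences that go with UMIs per cell were not tested. Within cluster 14 the medians were 0.06 for higher and −0.14 for lower genes, and within cluster 15 they were 0.12 and −0.22. Within cluster 16 they were 0.00 and −0.09. No random range was taken within clusters, so these medians cannot be set against one. Clusterin, the dose or time of LPS in each pool and chance between pools cannot be told apart with 1 library each.

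For the remaining comparisons the same regrouping was run. LPS in hippocampus had as many calls in 1 of 35 splits, the real one with 1687, and the highest other split had 0. LPS in cortex had as many in 1 of 100, the real one with 506, and the highest other split had 17. Where the real count is 0, every split reaches it by construction, so the regrouping tests nothing: this holds for CP plasma after LPS (35 of 35 splits), where another split called 1088. It holds as well for RP plasma after LPS (35 of 35, highest other 0), RP against CP plasma after LPS (35 of 35, highest other 1) and clusterin in cortex (100 of 100, highest other 2).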

How the results depend on the processing

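Alternatives with the choroid plexus score, the Ttr minimum, the cortex depth minimum, the L number factor and 2 further rules for naming clusters were chosen only after the results were seen, and the others before. Counts of 0 for CP plasma after LPS, RP against CP plasma after LPS and clusterin in cortex stayed 0 under every alternative. LPS in cortex stayed between 343 and 521 genes, LPS over Sal in endothelial cells between 448 and 847 and APP+Sal over APP between 85 and 174. The median of LPS-raised genes in RP against CP plasma after LPS stayed between −0.341, in the set with an absolute log2 fold change of 0.5 or more, and −0.092; with 1 L number left out it ran from −0.248 to −0.092 (without LPS_CP L15). Where values moved, the cause was not tested unless stated. The lowest total was 856540 counts, in cortex.

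LPS in hippocampus gave 2760 genes with each sample as a replicate, where more samples enter the test; with L numbers left out in turn it gave 1201 to 1730. RP plasma after LPS gave 39 genes with DESeq2, 9 with only the compared groups, 46 with each sample as a replicate and 32 with limma-voom. RP against CP plasma without LPS gave 268 with DESeq2, 0 with the choroid plexus score, 0 with only samples at 200 CPM of Ttr or more (3 of them RP), and 3 to 619 with a sample left out.

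Over all genes, the numbers that samples share showed no clear pairing. Correlations of deviations ran from −0.13 to 0.36 without LPS and from −0.23 to 0.30 in cortex. Not every sample correlated best with its own number. Lcn2 was highest of its group in both CP1 (26.07 CPM) and RP1 (19.45 CPM), so a shared source in some genes is not excluded. With the number as a replicate block, RP against CP plasma without LPS gave 19 genes, LPS in cortex 343 and clusterin in cortex 0. With consecutive L numbers as a replicate block, LPS in hippocampus gave 1911 genes and each plasma comparison 0. No paired analysis was possible because only 1 library stands in each group for the endothelial ratios.

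For LPS-regulated sets in RP against CP plasma after LPS, the lowered genes had 0.041 with an estimated correlation, past no threshold, and −0.007 (without LPS_CP L15, the reverse sign) to 0.065 with an L number left out. Without LPS, the raised genes ran from −0.093 to −0.006 over all alternatives. They had −0.027 with an estimated correlation, −0.006 with the choroid plexus score, −0.016 with the Ttr minimum and −0.04 to −0.019 with a sample left out. There the lowered genes had −0.062 in the set with an absolute log2 fold change of 0.5 or more, 0.004 with each sample as a replicate, 0.01 with the choroid plexus score, 0.014 with the Ttr minimum and −0.018 to 0.003 with a sample left out. In cortex the raised genes had −0.063 with the letters exchanged, −0.005 in the set of 0.5 or more and −0.047 to 0.07 with a sample left out, and the lowered genes 0.036 with the letters exchanged and −0.061 to −0.008 with a sample left out. Of 30 lists, those past camera went from 16 to 8 with an estimated correlation and to 18 with fry for LPS in hippocampus. They went to 0 with an estimated correlation and to 0 with fry for CP plasma after LPS (from 5), RP plasma after LPS (20), RP against CP plasma after LPS (18), RP against CP plasma without LPS (10) and clusterin in cortex (7).

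In endothelial cells, looser cell filters (200 genes, 20% mitochondrial) gave LPS+Clu over LPS ratios of 0.84 for Hba-a1, 0.65 for Hba-a2 and 0.54 for Hbb-bs, and −0.42 for Ttr in APP+Clu over APP+Sal, all of reversed sign. There the APP+Clu count was 9 and the APP-lower set 0.713. Stricter filters (1000 genes, 5%) reversed the same genes (0.84, 0.64, 0.54 and −1.61) and gave −0.33 for the LPS-lower set, −0.493 for the APP-higher set and 2.615 for the APP-lower set. With doublets kept, LPS over Sal reversed for Hba-a1 (0.78), Hbb-bs (1.33) and Hbb-bt (0.58), LPS+Clu over LPS for Hba-a1 (0.81), Hba-a2 (0.61) and Hbb-bs (0.51), and APP+Clu over APP+Sal for Hba-a1 (−0.41), Hba-a2 (−0.38), Hbb-bs (−1.14) and Ttr (−1.24); the LPS-lower set had −0.369. Leaving out clusters led by another class gave 47 genes for LPS+Clu over LPS, 0.259 and −0.47 for the LPS-higher and LPS-lower sets, and −0.315 and 0.711 for the APP sets. Counting vessel genes as another class reversed Vegfc in APP+Sal over APP (0.02) and gave −0.378 for the LPS-lower and 0.783 for the APP-lower set. A gate on marker genes in place of clusters reversed Hbb-bt in LPS over Sal (0.06) and Hba-a2 (−0.22) and Ttr (−1.38) in APP+Clu over APP+Sal, with 0.151, −0.366 and −0.211 for the LPS-higher, LPS-lower and APP-higher sets. Thinned cells reversed Ttr (−1.04) and gave 0.181, −0.391 and −0.35 for the same sets. A pseudocount of 1 gave 25 genes for LPS+Clu over LPS, 24 for APP over WT, −0.381 for the LPS-lower and 0.819 for the APP-lower set, and a mean of 50 CPM gave 6 genes for LPS+Clu over LPS. The APP-lower set had too few genes for a value under 4 of 9 alternatives.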

Other observations

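Tests of the L number structure and the LPS set within its strata were chosen only after the result was seen; the other values here were part of the planned tables.

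Further genes set the saline-treated APP endothelium apart from the untreated one. Beside Dbp, Nr1d1 and Nr1d2, the early response gene Fos was lower (−1.33), and the glucose transporter gene Slc2a1 (1.10) and Cdkn1a (1.71) were higher. Guanylate-binding Gbp3 (−1.47) and B2m (−1.08) were lower. The metallothioneins, which bind metals and respond to glucocorticoids, were high after LPS in endothelium (log2 ratio 4.70 for Mt2 and 4.01 for Mt1), and Mt2 was lower in APP+Clu than in APP+Sal (−0.99) while Mt1 (0.83) and Mt2 (0.75) were higher in LPS+Clu than in LPS. In endothelium after LPS, the apolipoprotein genes Apod and Clu were at 4.83 and 0.73 and Apoe at −2.14.

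Markers of other cells differed in the endothelial class. P2ry12 of microglia was at 0.1207 CPM or less, Aqp4 of astrocytes at 0.216 or less and S100a8 of neutrophils at 0.5416 or less in every library. Rgs5 of pericytes was at 32.17 to 135.2 CPM, Ttr at 0 to 114.6 CPM and the haemoglobin gene Hbb-bs at 0.5416 CPM in LPS+Clu, 351.1 in Sal and 1745 in WT. Pericytes made up 0.56% of cells in Sal, 0.838% in LPS, 0.614% in LPS+Clu, 2.03% in WT, 0.268% in APP, 0.488% in APP+Sal and 0.875% in APP+Clu. Both sexes seem to be pooled in WT and APP, where Xist was at 299 and 279 CPM beside Ddx3y at 78.3 and 62.7, while Xist was at 0.1207 CPM or less in the other libraries. The median share of mitochondrial UMIs was 4.94% in APP+Sal and 4.57% in APP+Clu, against 2.29% to 3.51% elsewhere.

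In hippocampus, LPS_RP L8_2 had the olfactory marker gene Omp at 9.904 CPM, against 2.938 or less in all other samples of its table. Lcn2 was at 51.18 CPM in SAL_SAL L5_2 and 30.0 in SAL_SAL L9_2, above the other saline samples.

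The L numbers up to 8 and over 8 differed in 1111 of 16180 genes, 416 higher and 695 lower over 8, with each group split evenly between both ranges. The division was found through the 1088 calls of another split in the comparison of CP plasma, so the 1111 genes are not independent evidence for it. It could reflect a batch that the labels do not give. The same division called 0 genes among LPS_SAL and SAL_SAL, 0 among LPS_SAL and LPS_RP and at most 1 among LPS_CP and LPS_RP. With the division as a factor LPS in hippocampus gave 1913 genes and each plasma comparison 0. Within these strata the exact permutation p of the LPS-raised score between RP and CP plasma was 0.111, where 36 arrangements allow 0.0556 at least.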
